A study of Mus musculus with 3 samples.

How the data were processed

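The deposited files come from 3 libraries of 1 group. Mouse bone-marrow-derived macrophages of strain C57BL/6J, cultured from marrow progenitors, received 100 ng/ml Lipid A for 12 hours, were washed and rested for 12 hours, and received 100 ng/ml Lipid A again for 50 minutes, per the labels. Lipid A is the membrane anchor of bacterial lipopolysaccharide and the part that Toll-like receptor 4 recognises. RNA of the chromatin fraction, which holds RNA still being made or retained on chromatin, was depleted of ribosomal RNA and sequenced as total RNA. The labels give a starting amount of 1 µg for replicate 1, 250 ng for replicate 2 and 500 ng for replicate 3, and a size range of 250 to 400 whose unit they do not give. The labels number the libraries as biological replicates 1, 2 and 3 and name the same donor for all of them. Nothing says that they came from separate animals or cultures, so the spread between libraries may be technical, and SDs and sign-flip p-values measure only the spread between these samples.

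Each library has gene and transcript tables made by alignment and a transcript table made directly from the reads. Per the file headers and the text deposited with each library, reads were placed on mouse build mm10 with GENCODE M21 annotation. The alignment-based tables derive from reads aligned to the transcriptome, and the read-based table derives from the reads and an index. The programs are not given in the sources used here. The column layout is that of RSEM output for the alignment-based tables and of kallisto output for the read-based table. The expected counts deposited by the authors are estimated reads or fragments per gene that need not be whole. The deposited TPM values are relative abundances corrected for effective length that sum to the same fixed total in each library over annotated genes, transfer RNA features and spike-in sequences. The alignment-based gene tables also hold a posterior mean TPM with a credible interval whose level is not given in the sources used here. Whether either quantification used the strand of the reads is also not given there. Values of genes that overlap another gene, or that have near-identical copies, are therefore uncertain. All 55536 gene identifiers matched the GENCODE M21 annotation, which supplied symbols, biotypes and mm10 coordinates.

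Depth was 13897176, 19597343 and 19348626 expected counts in replicates 1, 2 and 3, and 20743071, 34961536 and 32857771 estimated counts in the read-based tables. A count of 0 allows up to 3 counts, and the TPM that 3 counts would give was computed per gene and library. Such floors cover counting error only, and reads carried no molecular identifiers as far as the labels tell. The deposited credible intervals describe 1 library at a time and do not cover the spread between libraries. Short RNAs have effective lengths near 0, so a few counts can give a high TPM, and an effective length of 0 gives a TPM of 0 in spite of counts.

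With 1 group, no change with treatment could be tested. The measurements are levels, the spread between the 3 libraries, and comparisons of gene groups within the same libraries. All choices below were fixed before the data were examined, except where the text says otherwise. A gene was called detected at a TPM of at least 1 in every library. Agreement between libraries was the Pearson correlation across genes of log2(TPM + 1), over genes with a mean TPM of at least 1. Correlations across genes are not correlations across independent replicates. Before libraries were averaged, a chi-square test of their counts over genes was used to look for a library deposited more than 1 time. Chi-square per degree of freedom lay between 53.2 and 133 for the 3 pairs, so no pair agreed within counting noise and none was treated as a repeat deposit. The biological coefficient of variation came from edgeR 4.0.16 in R 4.3.3 with an intercept-only design, TMM scaling and the filterByExpr filter, on expected counts rounded to whole numbers. On simulated counts with a coefficient of variation of 20% for 5820 genes, the same function returned 20.1%. The same simulation changed 200 of 6020 genes 4-fold in 1 library, and 190 of the 200 were among the 200 highest coefficients of variation. Both checks used fewer genes and a smaller coefficient of variation than the data, for which edgeR gave 28.1% over 13184 genes. They therefore do not show how well that estimate, or a ranking of genes with few counts by coefficient of variation, performs.

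The 27 gene lists hold 415 distinct genes. They cover cell identity, markers of 7 kinds of other cells, the inflammatory response and its regulators, alternative activation, metabolism, mitochondrial and ribosomal genes, nuclear noncoding RNAs, histones, proliferation, cholesterol and stress. Where a symbol had 2 gene entries (3 symbols), the entry with the higher mean TPM was used. The median of log2(mean TPM + 1) of each list was set against 10000 random lists of the same size drawn from protein-coding nuclear genes, two-sided, with Benjamini-Hochberg adjustment over the lists. On simulated lists of 16 genes drawn from 22015 genes, 2.6% of random lists and 100% of lists raised by 3 on the log2 scale had a p under 0.05. Then 10 pairs of lists were compared by the difference of their medians, with a permutation test of 100000 resamples over genes, two-sided, and Benjamini-Hochberg adjustment over the 10 pairs. On simulated pairs of 16 and 20 genes from 9438 genes, 4.6% of pairs from the same population and 99.5% of pairs set 3 apart had a p under 0.05. The 9438 genes had a mean TPM of at least 1, whereas some list members lay below it. The list pairs were also judged by adjusted p. The 99.5% therefore does not carry over to them. Antimicrobial effectors and alternative activation markers, for example, differed by 5.14 with an adjusted p of 0.0684. A pair that missed the threshold is not shown to be without a difference. The list and pair tests take genes as the units, so they place gene groups within these libraries and say nothing about other cultures. The direction in each library was also tested by an exact sign-flip test, whose smallest p with 3 libraries is 0.25.

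The retained-intron share is the percent of a gene's TPM in transcripts annotated as retained intron. It was taken in genes with a mean TPM of at least 5 that have both a protein-coding and a retained-intron transcript. The 2 quantifications were compared by the genes whose TPM differed over 2-fold, with a pseudocount of 1, the same way in all 3 libraries. The genes named in the text are, for each list, the 3 members with the highest mean TPM and the lowest member. Added to these are 35 fixed genes of the response, the 10 highest protein-coding nuclear genes, the 5 highest other genes, the 10 genes with the highest coefficient of variation at a mean TPM of at least 10, and the 5 highest retained-intron shares at a mean TPM of at least 20. Some genes that this rule names are not reported here. Any other gene named was chosen after its values were seen.

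Alternatives changed a choice at a time: the pseudocount (0.1), the TPM threshold (0.1 and 5), a filter on low values, the read-based tables, the posterior mean TPM, CPM (counts scaled to library size), DESeq2 1.42.0 size factors, length-matched random lists, means in place of medians, and each library left out in turn. After the data were seen, 2 more were added: protein-coding transcripts only for the list pairs, and a ranking by coefficient of variation of protein-coding genes with at least 100 counts in every library. FPKM columns and posterior counts were not used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the other computations.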

Results

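Chromatin-associated RNA was measured in 3 libraries of bone-marrow-derived macrophages that had met Lipid A, rested and met it again 50 minutes before harvest. All 3 libraries belong to this group, and untreated or singly treated cells were not analysed here, so each value is a level and not a response. Of 55536 annotated genes, 11228 had a TPM of at least 1 in all 3 libraries, 8638 of them among the 22028 protein-coding genes. The libraries held 12410, 13241 and 12364 such genes at 13897176, 19597343 and 19348626 expected counts for replicates 1, 2 and 3. Values are given as mean ± SD over n = 3 libraries unless a library is named.

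Noncoding RNAs took a large part of the reads. Malat1, a nuclear long noncoding RNA of splicing speckles, held 9.33% ± 0.248 (SD, n = 3) of all expected counts, and Neat1, the scaffold RNA of paraspeckles, held 1.48% ± 0.452. The largest share belonged to Gm26917, an annotated long noncoding RNA on chromosome 17 (39843013 to 39846341, mm10), at 16.4% ± 4.88. It ends just before the ribosomal RNA entry CT010467.1 (39846353 to 39848827), and Gm42418 (39846958 to 39848788) lies inside that entry; both were named after their values were seen. CT010467.1 held 0.668% ± 0.485 and Gm42418 1.77% ± 0.819. All 3 were lowest in replicate 1, with shares in replicates 1, 2 and 3 of 10.8%, 18.2% and 20.1% for Gm26917, 0.822%, 2.30% and 2.18% for Gm42418 and 0.121%, 1.05% and 0.836% for CT010467.1, so how much of these shares is remaining ribosomal RNA is not known. Protein-coding genes held 62.1% ± 4.41 of counts and long intergenic noncoding RNAs, Gm26917 and Gm42418 included, 30.9% ± 5.56.

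Length-corrected units gave another ranking. Small nucleolar RNAs, which guide modification of ribosomal RNA, held 27.8% ± 3.52 of TPM and 0.235% ± 0.0943 of counts, and protein-coding genes held 28.5% ± 1.00 of TPM. The 5 highest genes outside the protein-coding set were the small nucleolar RNA genes Gm22988 (82438 ± 36600 TPM), Gm26447 (43575 ± 16496) and Snord15b (34467 ± 7504), the ribozyme RNA Rmrp (69592 ± 34087, but 28623 ± 5886 in the read-based tables) and Gm26917 (58472 ± 20960). The TPM of a gene covers all its transcripts, and for Lilrb4a nearly all of it lay in transcripts annotated as retained intron. Among protein-coding genes the highest were Lilrb4a (2760 ± 913 TPM) and Lilr4b (1994 ± 663), neighbouring receptor genes on chromosome 10 whose shared sequence makes the split between them uncertain. They were followed by H2-K1 (1920.1 ± 360.3), a class I histocompatibility gene, Tnfaip2 (1667 ± 437), Acod1 (1436 ± 414), Zeb2 (1407 ± 229), Malt1 (1327 ± 380), Ikbke (1300.5 ± 211), Mx1 (1207 ± 257) and Sirpa (1206 ± 156).

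The question of the inflammatory genes was how high each group stood 50 minutes after the second exposure. Interferon-stimulated genes were the highest of the response groups: all 28 had a TPM of at least 1 in all 3 libraries, with a median of 240.1 TPM. Mx1, an antiviral GTPase, stood at 1207 ± 257 TPM, the transcription factor gene Irf1 at 781 ± 147, and Rsad2, which encodes viperin, at 779 ± 489, while the lowest member, Bst2, stood at 50.8 ± 20.8. Chemokine genes had a median of 94.6 TPM and 12 of 15 were detected, led by Ccl5 (742 ± 285), Cxcl2 (487 ± 202) and Cxcl10 (375 ± 245). The 3 not detected in all libraries were Cxcl9 (0.217 ± 0.172), Cxcl3 and Ccl22, of which the last 2 were named after their values were seen. Both lists lay above random lists of protein-coding genes, each at an adjusted p of 0.0006 (permutation test over genes, Benjamini-Hochberg over 27 lists). The p before adjustment was 0.0002 for both, the smallest these random lists can give.

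Inflammatory cytokine genes were divided. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) stood at 564 ± 130 TPM, Il1b at 336 ± 86.2 and Il1a at 196 ± 68.1. The genes of 3 other fixed cytokines were far lower: Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981) at 9.82 ± 7.69, Il12b at 7.22 ± 3.95 and Ifnb1, the interferon beta gene, at 4.76 ± 4.5. The median of the 16 cytokine genes was 5.99 TPM, 9 of them were detected in all libraries, and the list did not pass the test (adjusted p = 0.052). Without replicate 2 the same list passed, at an adjusted p of 0.0126, as it did against length-matched random lists (0.0137), and over all alternatives its adjusted p ran from 0.0126 to 0.820.

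Negative regulators of Toll-like receptor and NF-kB signalling were present at substantial levels. Of 22 genes, 21 were detected, with a median of 39.5 TPM and an adjusted p of 0.0006. The highest were Tnip3 (658 ± 59.0 TPM), Tnfaip3 (592 ± 165), which encodes the ubiquitin-editing protein A20, and Nfkbiz (379 ± 91.6), and Nfkbia, which encodes the inhibitor IkB-alpha, stood at 331 ± 75.8. Most of the Tnip3 value lay in transcripts annotated as retained intron. Socs3 reached 95.8 ± 20.7, Irak3, which encodes the inhibitory kinase-like protein IRAK-M, 38.0 ± 6.71, Il1rn 29.8 ± 16.9 and Il10 12.0 ± 9.51, while Socs1 stood at 1.73 ± 0.144. Sigirr, at 0.25 ± 0.0917, was the member not detected. Genes of the receptor pathway itself (26 of 27 detected, median 41.5 TPM, adjusted p = 0.0006) included Ikbke at 1300.5 ± 211, Irak2 at 228 ± 15.6 and Tbk1 at 228 ± 29.3. The receptor gene Tlr4 stood at 8.81 ± 0.0361 TPM, its partner Ly96 at 11.2 ± 2.87 and the co-receptor gene Cd14 at 115 ± 66.5, with 192 TPM in replicate 3 against 76.4 and 77.0 in replicates 1 and 2. The lowest member of the pathway, Tirap, stood at 1.31 ± 0.526.

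Immediate-early genes were detected in 20 of 22 cases, with a median of 19.6 TPM and an adjusted p of 0.0006. Klf6 (279 ± 86.3 TPM), the RNA-decay factor gene Zfp36 (139 ± 41.3) and the phosphatase gene Dusp1 (138 ± 33.2) led the list, and Egr1 (48.5 ± 21) and Fos (12.7 ± 4.14) stood lower. Fosl1 had 0 counts in each library, where 3 counts would have been 0.300, 0.254 and 0.273 TPM, and Fosb, named after its values were seen, stood at 0.470. Antimicrobial effector genes (15 of 19 detected, median 39.8 TPM, adjusted p = 0.0006) were led by Acod1 (1436 ± 414), which encodes the enzyme that makes itaconate, the lectin receptor gene Clec4e (868 ± 286) and the oxidase gene Cybb (483 ± 99.7). Saa3 stood at 254 ± 39.1 and Marco at 66.8 ± 12.5, whereas Nos2, the inducible nitric oxide synthase gene, stood at 8.82 ± 5.91 and Lcn2 at 2.06 ± 0.659. The 4 members below the threshold were Camp, Slpi, Hp and Hamp, the last with 0 counts in each library; Slpi and Hp were named after their values were seen.

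**Figure D1:**
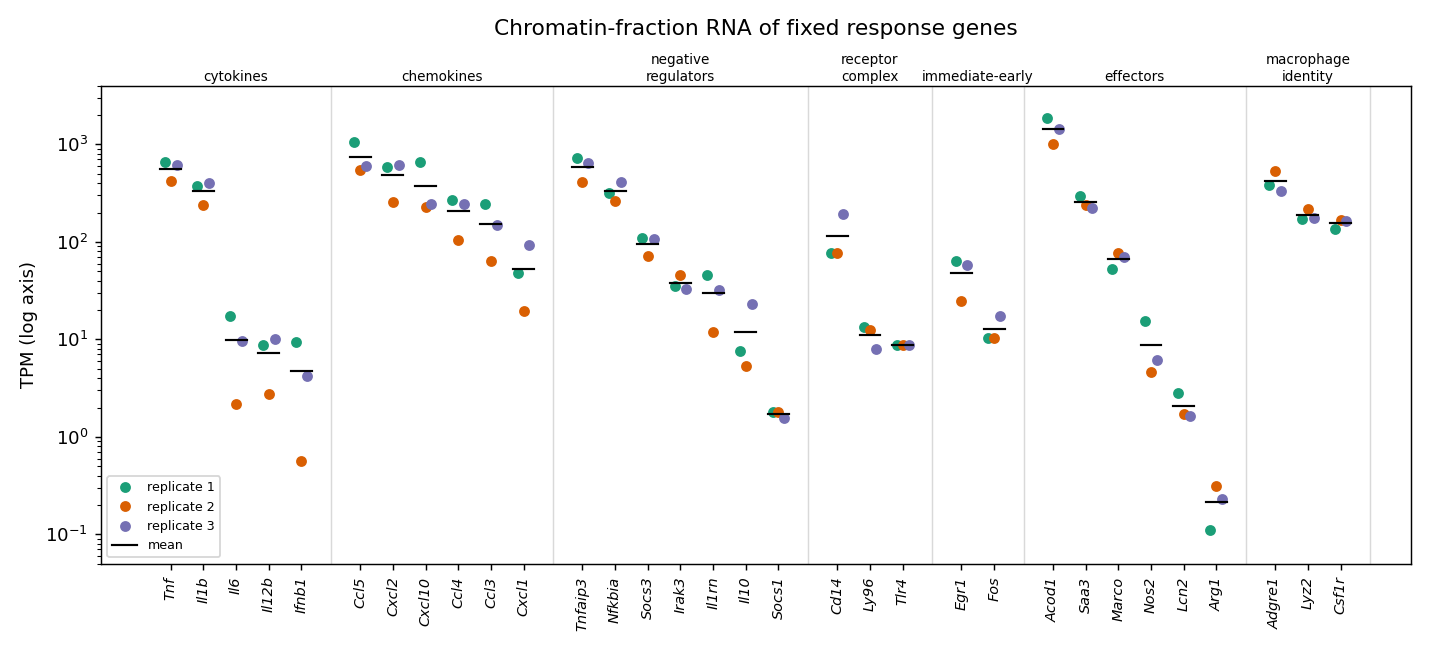
TPM (log axis) of fixed response genes in each of the 3 libraries, with points for replicates and bars for their mean, grouped by kind of gene. Tnf and Tnfaip3 stood at 564 and 592 TPM, Il6 and Ifnb1 at 9.82 and 4.76, and the points of replicate 2 lay lowest for each cytokine gene shown.

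Direct comparison of the groups showed that immediate-early genes stood below interferon-stimulated genes. Their medians differed by -3.55 on the log2(TPM + 1) scale, 11.7-fold, with an adjusted p of 0.0001 (permutation test over genes, Benjamini-Hochberg over 10 pairs) and the same sign in 3 of 3 libraries (-3.31 ± 0.53). The p before adjustment was 1e-05, the smallest these permutations can give. With protein-coding transcripts alone, an alternative added after the data were seen, the difference was -2.09, 4.26-fold (adjusted p = 9e-05, range over alternatives 3.33e-05 to 0.0002). Cytokine genes stood below negative regulators by -2.56 (adjusted p = 0.0726), below antimicrobial effectors by -2.57 (adjusted p = 0.204), and chemokines below interferon-stimulated genes by -1.33 (adjusted p = 0.083). Each had the same sign in 3 of 3 libraries and none of the 3 passed the permutation test over genes. The exact sign-flip p of each of these comparisons was 0.25, the smallest that 3 libraries allow. With the read-based tables the cytokine and regulator lists differed by -3.23 and passed (adjusted p = 0.0369, range over alternatives 0.0369 to 0.202), but by -1.62 with protein-coding transcripts alone (3.07-fold against 5.88-fold), -1.67 with means and -1.95 among genes with a mean TPM of at least 1. The cytokine and effector lists differed by -3.44 with that filter and by -1.53 with means, neither of which passed (adjusted p = 0.195 and 0.201, range 0.113 to 0.233). With counts scaled to library size (CPM) the chemokine and interferon-stimulated lists differed by -2.35 (adjusted p = 0.00472, range 0.00273 to 0.264), and with means by -2.27, but by -0.70 with protein-coding transcripts alone (1.62-fold against 2.52-fold).

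The identity of the cells was read from marker lists. Macrophage genes were high: 23 of 24 were detected, with a median of 45.0 TPM and an adjusted p of 0.0006, led by Adgre1 (418 ± 109 TPM), which encodes the macrophage surface protein F4/80, the scavenger receptor gene Msr1 (255 ± 55.3) and the lysozyme gene Lyz2 (188 ± 26.1). Csf1r, the receptor gene for the growth factor that macrophages depend on, stood at 155 ± 18.4, and Cebpa at 0.290 ± 0.105 was the member not detected. Neutrophil markers were near 0 in the alignment-based tables of all libraries: none of 14 was detected, and the highest, S100a9, had 0 counts in replicates 1 and 3 and 2 counts in replicate 2, 0.430 TPM. Cxcr2, named after its values were seen, had 0 counts in each library but 4.05 ± 0.431 TPM in the read-based tables. Dendritic cell markers behaved likewise, with 0 of 9 detected and Clec9a highest at 0.550 ± 0.532. Macrophage genes lay above neutrophil markers by 5.44 (adjusted p = 0.00905) and above dendritic cell markers by 5.41 (adjusted p = 0.0003) in median log2(TPM + 1), with the same sign in 3 of 3 libraries (permutation test over genes). The size depends on the pseudocount, since both marker lists lay near 0: with a pseudocount of 0.1 the differences were 8.15 (284-fold against 43.4-fold) and 7.97 (250.1-fold against 42.5-fold). With the read-based tables the neutrophil difference was 6.08 (67.6-fold).

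Markers of other cells were low as well. No B cell marker was detected (highest Fcer2a, 0.303 ± 0.120 TPM, but 13.6 ± 0.980 in the read-based tables), and no marker of mast cells, basophils or eosinophils was (highest Kit, 0.810 ± 0.536). Of 14 T and natural killer cell markers, Cd4 was detected at 2.98 ± 0.376 TPM while Lck stood at 0.243 ± 0.0723. Cd3d and Cd8a, named after their values were seen, stood at 15.7 ± 3.18 and 1.57 ± 0.173 TPM in the read-based tables, against 0 counts in each library for Cd3d and 1 or 2 for Cd8a in the alignment-based tables. Of 10 stromal and endothelial markers, Kdr was detected, at 8.92 TPM in replicate 1 and 2.27 and 2.01 in replicates 2 and 3. Of 10 erythroid and megakaryocyte markers, the heme synthesis gene Alas2 (5.55 ± 1.05, and 13.7 ± 2.99 in the read-based tables) and the integrin gene Itga2b (2.42 ± 0.704) were detected. In the read-based tables this list lay below random lists (adjusted p = 0.0479). None of these 5 lists, nor the neutrophil and dendritic cell lists, lay above random protein-coding lists (adjusted p from 0.155 to 0.675, permutation test over genes). The median of protein-coding genes was itself 0.45 on the log2(TPM + 1) scale. With the alignment-based tables this test could not have placed the 7 lists below. A median of 0, the lowest possible, gave p values before adjustment of 0.0978 for 14 genes, 0.131 for 10 and 0.247 for 9. Alternative activation markers had a median of 0.162 TPM (adjusted p = 0.675). Mrc1, the mannose receptor gene, at 47.1 ± 11.9 TPM and Il4ra at 31 ± 16.8 were the 2 detected of 12, and Arg1, the arginase gene, stood at 0.217 ± 0.101. Antimicrobial effectors exceeded this list by 5.14 in the median, with an adjusted p of 0.0684, and by 4.02 in the mean with an adjusted p of 0.00273 (range over alternatives 0.00273 to 0.555). Without replicate 2 or without replicate 3 the medians also passed, at 5.31 (adjusted p = 0.0427) and 5.30 (adjusted p = 0.0376). Among genes with a mean TPM of at least 1, which left 15 effectors and 3 of these markers, the difference was 1.88, 3.67-fold (adjusted p = 0.555).

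**Figure D2:**
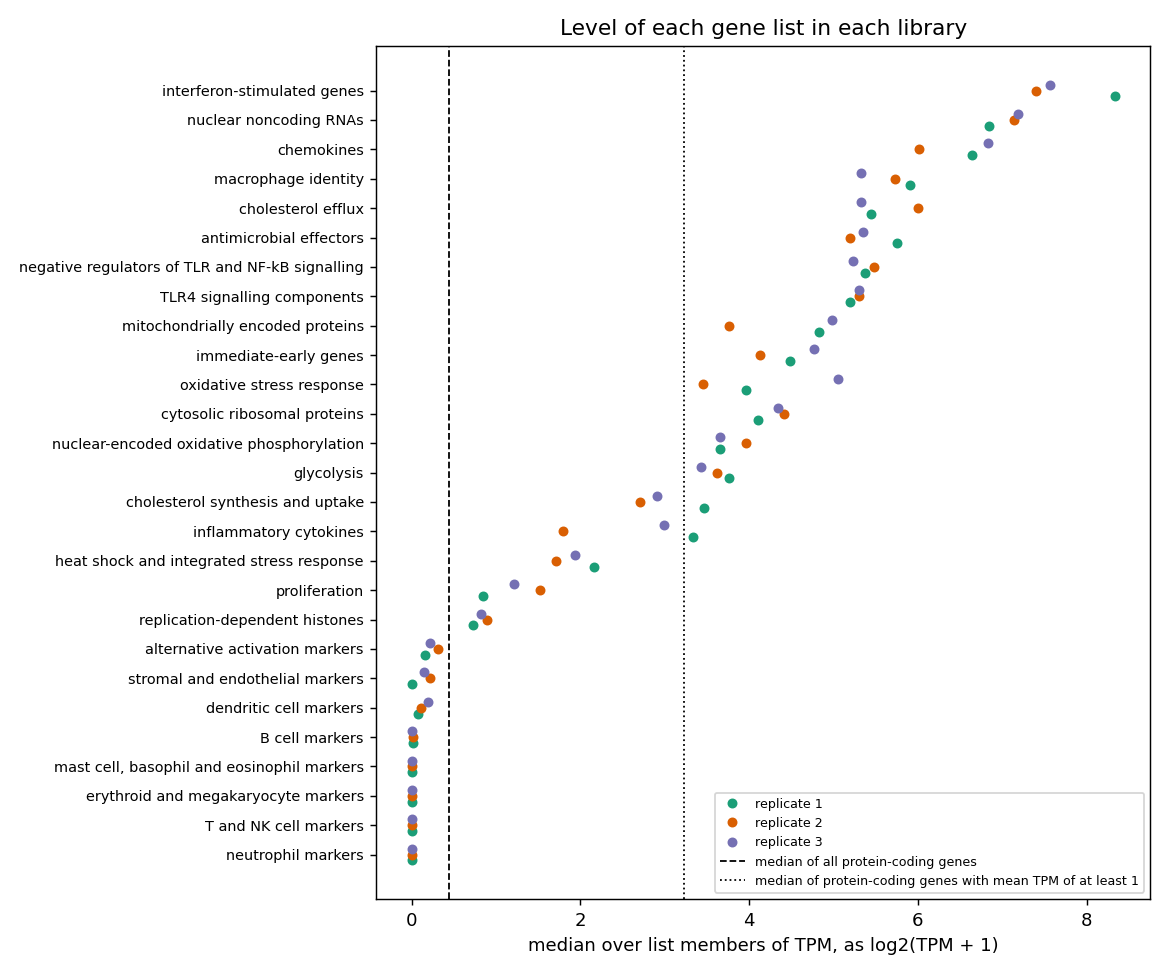
Median level of the 27 gene lists in each library, as log2(TPM + 1), with points for replicates and lines for the median of all protein-coding genes (0.45) and of those with a mean TPM of at least 1 (3.22). Interferon-stimulated genes lay highest of the protein-coding lists, and markers of other cells lay near 0 in all 3 libraries.

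The 18 glycolysis genes had a median of 12.2 TPM (adjusted p = 0.0009 against random lists, permutation test over genes), led by Hk3 (344 ± 57.2), Pkm (69.7 ± 16.8) and Pfkp (48.3 ± 11.1), with the glucose transporter gene Slc2a1 lowest at 1.95 ± 0.565. The 18 nuclear genes of oxidative phosphorylation had a median of 12.5 TPM (adjusted p = 0.0009), led by Atp5b (69.9 ± 19.0), Sdha (31 ± 3.15) and Atp5a1 (20.4 ± 2.32), with Ndufa4 lowest at 1.23 ± 0.338. The medians differed by -0.044 (adjusted p = 0.956, permutation test over genes), with 2 of 3 libraries on the negative side, and the sign turned with CPM, means, posterior mean TPM and protein-coding transcripts. The 20 ribosomal protein genes had a median of 17.9 TPM (adjusted p = 0.0006), from Rplp1 at 6.45 ± 1.46 to Rpl5 at 43.0 ± 10.6, Rpl3 at 45.9 ± 17.5 and Rpl10 at 100.3 ± 18. They lay below nuclear noncoding RNAs by -2.81 (adjusted p = 0.0003, permutation test over genes), 7.04-fold, in 3 of 3 libraries. With CPM the difference was -3.95 (15.4-fold) and with means -3.53 (11.5-fold). That noncoding list had a median of 132 TPM with 14 of 16 detected (adjusted p = 0.0006). Rmrp, Malat1 (24577 ± 5111) and the 7SK RNA gene Rn7sk (14882 ± 4531, and 8356 ± 3320 in the read-based tables) led it, Ptgs2os2 stood at 1.72 ± 0.982, and Meg3 had 0 counts in each library.

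Cholesterol efflux genes were all detected, with a median of 43.4 TPM (6 genes, adjusted p = 0.00125 against random lists, permutation test over genes). The transporter gene Abca1 stood at 203 ± 26.5, the nuclear receptor gene Nr1h3 at 73.9 ± 26.5, Pltp at 44.0 ± 20.4 and Apoe at 21.5 ± 3.29. Genes of cholesterol synthesis and uptake had a median of 7.36 TPM (14 of 16 detected, adjusted p = 0.0252), with Insig1 highest at 58.4 ± 18. The synthesis list did not pass without replicate 1 (adjusted p = 0.0533), in the read-based tables (0.0677) or against length-matched random lists (0.081; range over alternatives 0.0135 to 0.888). The difference of the medians of the efflux and synthesis lists, 2.41, had an adjusted p of 0.0802 and the same sign in 3 of 3 libraries. It passed with means (2.41, adjusted p = 0.0083), the read-based tables and protein-coding transcripts (range over alternatives 0.0083 to 0.195, permutation test over genes). Oxidative stress genes had a median of 18 TPM (9 of 10 detected, adjusted p = 0.0135), led by the autophagy receptor gene Sqstm1 (803 ± 295), Nfe2l2 (256 ± 77.2) and Txnrd1 (187 ± 65.9), with Nqo1 at 0.0900 ± 0.0693. Heat shock and integrated stress genes had a median of 2.57 TPM (8 of 11 detected) and did not pass the test (adjusted p = 0.347). They held Hspa8 at 111 ± 23.7, Ddit3 at 74.7 ± 30.6 and Atf4 at 41.9 ± 6.71, with Hspb1 at 0.910 ± 0.430.

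Proliferation genes had a median of 1.47 TPM and replication-dependent histone genes, whose transcripts lack poly(A) tails, had a median of 0.723 TPM. Mki67, a marker of cycling cells, stood at 116 ± 36.3 TPM, above Pcna (17.7 ± 3.82), Top2a (4.59 ± 2.23) and Ccnb2 (0.180 ± 0.0458), and the histone gene Hist2h2ac led its list at 3.78 ± 1.84. Neither list differed from random lists of all protein-coding genes (adjusted p = 0.481 and 0.722, permutation test over genes). Set against protein-coding genes with a mean TPM of at least 1, the expressed members of both lay below random lists, at adjusted p values of 0.0238 and 0.00577. In total 15 of 27 lists lay above random lists of all protein-coding genes and 0 below. With that filter 9 lay above and 2 below, but not all 27 could be tested. Too few members were left of some lists, the neutrophil and dendritic cell lists among them. For the short marker lists of other cells the 0 below was fixed in advance, since even a median of 0 would not have passed. The 6 that no longer passed were glycolysis, oxidative phosphorylation, mitochondrially encoded, ribosomal protein, cholesterol synthesis and oxidative stress genes, with adjusted p values from 0.111 to 0.888.

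Mitochondrially encoded genes held 0.0540% ± 0.0175 of TPM and 0.0396% ± 0.0178 of counts, and 8 of 13 were detected, with a median of 21.5 TPM (adjusted p = 0.0009, permutation test over genes). With CPM the list did not pass (adjusted p = 0.102, range over alternatives 0.000491 to 0.111). mt-Co1 stood at 183 ± 65.5 TPM, mt-Atp8 at 123 ± 33.5 and mt-Nd6 at 37.8 ± 15.9. mt-Co2, a subunit gene of cytochrome oxidase (mitochondrial positions 7013 to 7696), was listed at 0 in each library, while its annotated nuclear copies Gm28661 and Gm13341, named after their values were seen, held 81.0 ± 35.3 TPM. A single nuclear copy contains up to 99.5% of the 31-base words of mt-Co2, and the read-based tables listed mt-Co2 at 14.7 ± 4.19 TPM, so the value of this gene is uncertain. Nuclear copies share at least 98.1% of such words with mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l as well. These 5 are the members not detected, at 39.1 ± 26.2 TPM together against 229.6 ± 95.6 for their copies, so their values, the number detected and the mitochondrial share depend on how reads were split between genes and copies.

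Much of the signal within genes lay in transcripts annotated with a retained intron. Over 4290 genes the median retained-intron share was 45.1% ± 3.60 (46.1%, 48.0% and 41.1% in replicates 1, 2 and 3), and 1771 genes, 41.3%, had a share over 50%. Among lists with at least 6 eligible genes, ribosomal protein genes had the highest median share (73.1%, 16 genes), followed by chemokines (65.9%, 6 genes) and antimicrobial effectors (64.4%, 6 genes). Interferon-stimulated genes stood at 45.9% (16 genes), negative regulators at 35.6% (13 genes) and macrophage identity genes at 34.4% (10 genes). Rpl5 had a share of 95.2% ± 2.98, Ccl5 69.6% ± 4.23, Cxcl10 69.3% ± 9.91, Tnip3 85.7% ± 2.77 and Nfkbia 9.44% ± 1.02. The highest shares at a mean TPM of at least 20 were those of Lilrb4a (99.7% ± 0.435), Slc27a1 (99.5% ± 0.942), Spaca6 (99.4% ± 1.02), Rbm4b (98.7% ± 0.175) and Tmem132a (95.7% ± 2.28). For Tmem132a the main transcript of this kind, Tmem132a-203, lies on chromosome 19 from 10859138 to 10860508 and held 145 ± 32 TPM. All transcripts of a class took 16.1% ± 2.24 of counts for retained introns and 41.6% ± 1.70 for protein-coding transcripts. The share depends on which transcripts the annotation lists, and it does not separate unspliced precursor from a stable transcript.

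**Figure D3:**
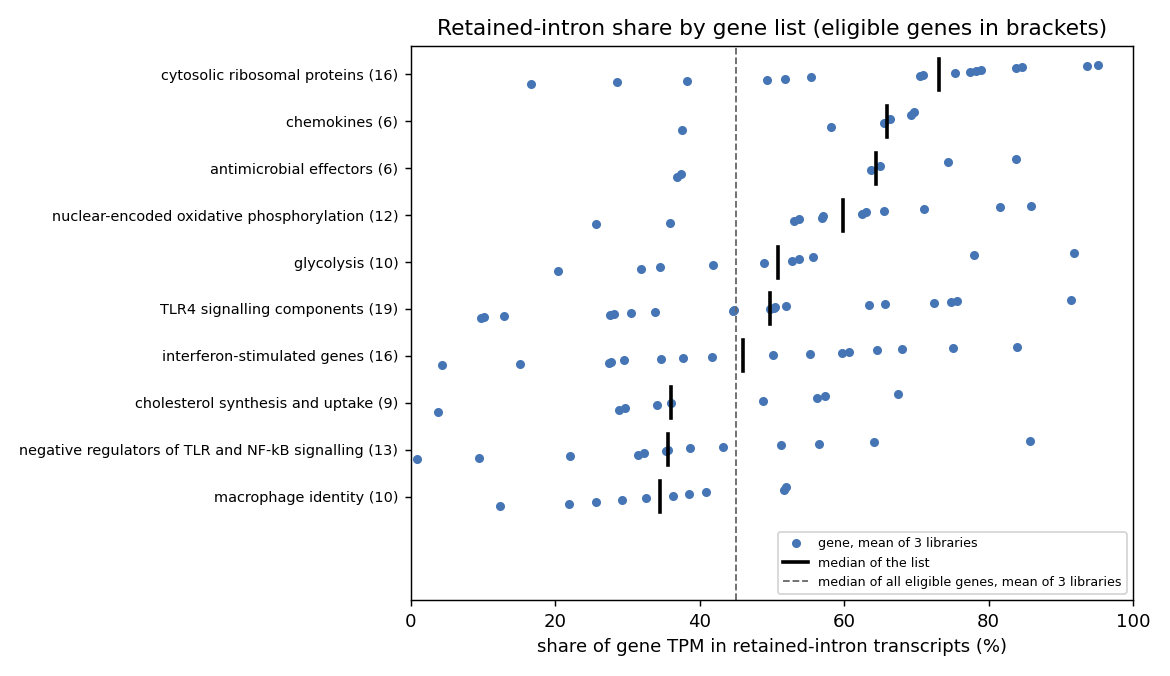
Retained-intron share of each eligible gene (points, percent of gene TPM, mean of 3 libraries) by gene list, with bars for list medians and a dashed line at the median of all 4290 genes (45.1%). Ribosomal protein genes had a median of 73.1% and macrophage identity genes 34.4%.

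The libraries differed from each other in identifiable genes. Of 9438 protein-coding genes with a mean TPM of at least 1, the median coefficient of variation was 24.0% (quartiles 14.9% and 36.0%), and for 4946 genes, 52.4%, the deposited credible intervals of the 3 libraries shared no common value. The Pearson correlation of log2(TPM + 1) across 12894 genes was 0.909 for replicates 1 and 2, 0.930 for 1 and 3 and 0.945 for 2 and 3. The common biological coefficient of variation was 28.1% (edgeR, 13184 genes). Relative to protein-coding genes as a whole, chemokine genes deviated by -0.90 (log2) in replicate 2 and by 0.70 in replicate 1, and 10 of 12 expressed members were lowest in replicate 2. Cytokine genes deviated by -0.84 in replicate 2 with 12 of 13 lowest there, and interferon-stimulated genes by 0.61 in replicate 1 and -0.43 in replicate 2. Other lists were also low in replicate 2. Mitochondrially encoded genes deviated by -0.79 there (9 of 12 lowest, of which mt-Atp6 tied with replicate 3 at 0 TPM). Their share of TPM was 0.0683%, 0.0344% and 0.0592% in replicates 1, 2 and 3. Among them, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l depend on how reads were split with nuclear copies. Oxidative stress genes deviated by -0.46, immediate-early genes by -0.43 (14 of 20 lowest), and heat shock and integrated stress genes by -0.40 (8 of 9 lowest). Of all 9438 protein-coding genes, 19.7% were lowest in replicate 2. Il6 illustrates the spread, at 17.6, 2.19 and 9.71 TPM in replicates 1, 2 and 3, as does Ifnb1 at 9.51, 0.560 and 4.21.

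**Figure D4:**
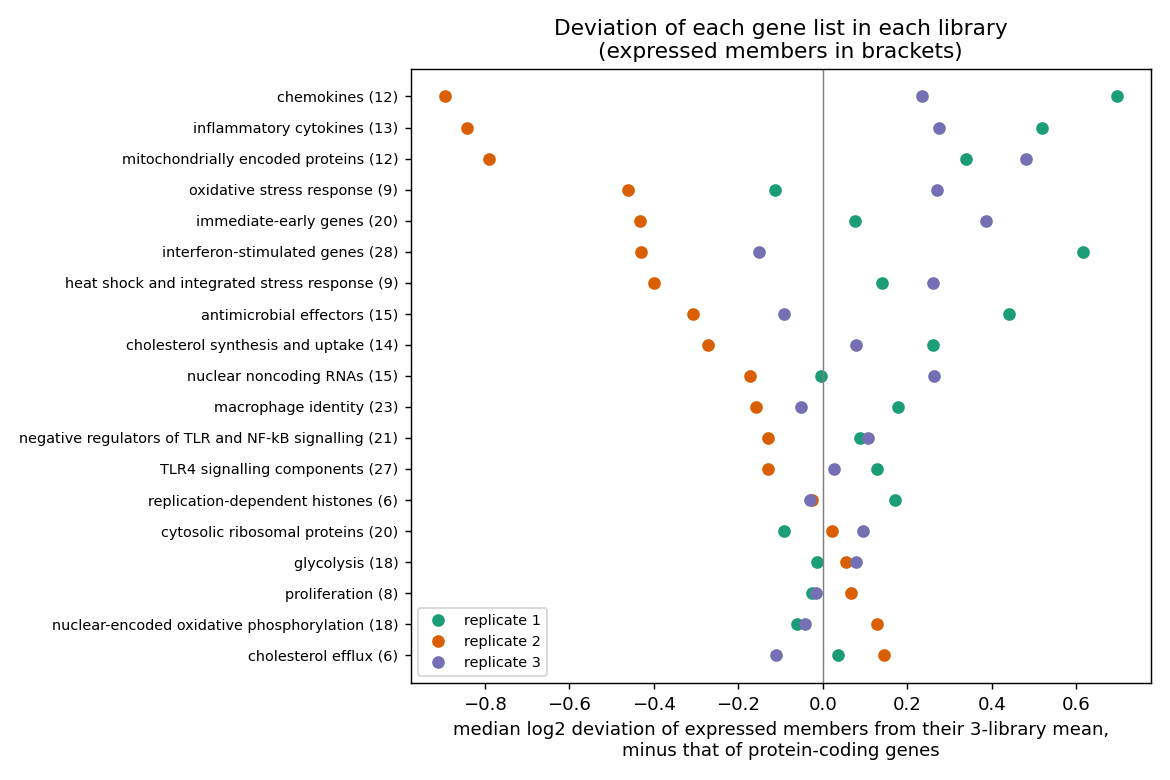
Median log2 deviation of the expressed members of each list from their mean over the 3 libraries, relative to protein-coding genes, with a point per replicate. Chemokines (-0.90), cytokines (-0.84) and mitochondrially encoded genes (-0.79) lay lowest in replicate 2, and lists such as ribosomal proteins (0.02) and glycolysis (0.05) lay near 0 there.

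The 10 genes with the highest coefficient of variation at a mean TPM of at least 10 were mostly short noncoding RNAs with a TPM above 0 in 1 library only. Snord22, a small nucleolar RNA, stood at 13084 TPM in replicate 1 and 0 in the others, although 330, 1231 and 715 counts were assigned to it in replicates 1, 2 and 3. Gm29216, a pseudogene of mitochondrial sequence on chromosome 1, had 386 counts in replicate 1 and 0 in the others. The other 8 (Gm47284, Gm25973, Gm24252, Gm23297, Gm25820, Gm23639, Snora43 and Gm22620) had at most 4 counts in any library. Among 4224 protein-coding genes with a mean TPM of at least 10 and at least 100 counts in every library, a ranking chosen after the data were seen, Ms4a4c varied most (266, 45.0 and 53.7 TPM in replicates 1, 2 and 3). The nucleotide kinase gene Cmpk2 (482, 93.7 and 159) and the receptor genes Il15ra (216, 69.7 and 55.8) and Axl (40.2, 10.1 and 14.4) were also highest in replicate 1, of which Axl is not among the 10 most variable after rescaling to the protein-coding total. The transporter genes Slc25a10 (12.9, 43.6 and 10.7) and Slc13a3 (18.2, 63.4 and 21.4) were highest in replicate 2. Il10 (7.63, 5.37 and 22.9) and the cystine transporter gene Slc7a11 (24.2, 8.88 and 51.0) were highest in replicate 3.

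The 2 quantifications of the same reads placed some genes differently. Of 55450 genes, 6669 differed over 2-fold the same way in all 3 libraries, 6596 of them higher in the read-based tables and 73 lower. All 6669 were among the 21129 genes with a mean TPM of at least 1 in either quantification. With a pseudocount of 1, genes near 0 in both could not be called different. Of the 415 list members, 28 were higher there and 0 lower. Those included the chemokine gene Ccl4 (206 ± 88.6 against 432 ± 173 TPM in the read-based tables) and the interleukin-1 receptor antagonist gene Il1rn (29.8 ± 16.9 against 64.7 ± 36.6). Tnf (613 ± 203), Tnfaip3 (783 ± 225) and Il6 (10.9 ± 8.99) stood within 2-fold of their alignment-based values. Over 9428 protein-coding nuclear genes with a mean alignment-based TPM of at least 1, 85.5%, 83.9% and 85.4% of values lay within 2-fold in replicates 1, 2 and 3. That set leaves out genes below this TPM that the read-based tables placed higher.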

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

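Of the tests in this part, those on Mki67, on library scaling, on the starting amount and on opposite-strand overlap and on overlap within expressed and other genes were chosen after the result was seen. Counts outside the main measurement were present in all 3 libraries, above the 3 counts that a count of 0 allows. The phiX sequencing control held 174289 counts in replicate 1, 40334 in replicate 2 and 50569 in replicate 3. Transfer RNA features held 27, 25 and 23 counts in replicates 1, 2 and 3.

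Mki67 (ENSMUSG00000031004.8, chromosome 7, 135689784 to 135716361, mm10) stood far above the other 14 proliferation genes, whose median was 1.15 ± 0.337 TPM, with ratios of 176, 54.0 and 107 in replicates 1, 2 and 3. For the level of Mki67 itself, a fault of 1 quantification alone is argued against by a ratio of 1.02 ± 0.0892 between read-based and alignment-based TPM. Among the other 14, Birc5, Cdk1 and Tyms were over 2-fold higher in the read-based tables in all 3 libraries. The ratios to the median of the 14 may thus depend on the quantification, and they were not computed from the read-based tables. An error shared by both, which start from the same reads, was not tested. The overlapping gene Gm45240, on the opposite strand with 0 shared exon bases, held 0.807% ± 0.176 as many counts as Mki67. No biological explanation was tested, cycling cells included, because the design has 1 group, and why Mki67 stands apart stays open.

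Of 25 expressed cytokine and chemokine genes, 22 were lowest in replicate 2, with a median deviation of -0.87 (log2). Library scaling as the whole cause would move all genes alike. It is argued against by the 19.7% of 9438 expressed protein-coding genes that were lowest in replicate 2, against 88% of the 25. The exact 95% intervals, 18.9% to 20.5% and 68.8% to 97.5%, take genes as independent, which genes that vary together within a library are not. They measure no spread between libraries, and the pattern was picked after the data were seen. A fault of 1 quantification alone is argued against by a deviation of -0.83 in the read-based tables, a test set before its result was seen. An error shared by both quantifications was not tested. The starting amount of RNA, 250 ng in replicate 2 and larger in the others, cannot be told apart from any other difference between libraries, since each amount has 1 library. No biological explanation was tested, because the design has 1 group.

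Genes higher in the read-based tables numbered 6596, of which 4666, 70.7%, overlapped no expressed gene, against 81.2% of all 55450 genes. Among genes not expressed in the alignment-based tables, 23.5% with an overlap on the opposite strand were higher against 10.5% with none, a ratio of 2.23. With an overlap on the same strand 29.1% were higher, a ratio of 2.76. Both lay above the limit of 2 set for the test. Among expressed genes the ratios were 1.24 and 0.981 (11.5% and 9.11% against 9.29%). This split cannot decide for or against a cause, because the alignment-based value that sorts the genes is also part of the difference tested. Over all genes the ratios were 1.69 and 2.00. That settles neither counting without strand nor reads of an overlapping gene on the same strand. A comparison of the strands with each other gave a ratio of 0.844 over all genes (17.5% opposite against 20.8% same). It had no limit set for it and is not counted as a test set before the data were examined. Counting without strand as the main source would raise the opposite-strand share more, which was not seen over all genes. Reads of an overlapping gene may raise the same-strand share, so a smaller part of strand stays open. No biological explanation was tested, since the same reads underlie both tables.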

How the results depend on the processing

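The alternative restricted to protein-coding transcripts was added after the data were seen. Of 97 alternatives to the 10 comparisons of lists, 80 kept direction and side of the threshold, 13 passed a threshold missed before and 4 reversed; the cause was not tested unless stated. Of 52 alternatives to the 8 other results, 41 stayed within 1 SD, or within 1.5 times for a count, and 11 moved. Detected genes numbered 16446 at a TPM of 0.1, 6334 at a TPM of 5 and 18083 in the read-based tables (11228 before). The mean correlation of libraries, 0.928, became 0.882 with a pseudocount of 0.1 and 0.973 with no filter. The biological coefficient of variation ran from 24.7% to 32.4% (without replicate 3) with a library left out. Lists above random lists fell from 15 to 9 with the filter on low values, which also raises the background and leaves some lists with too few members to test. Lists below numbered 2 with the filter and 1 in the read-based tables. The read-based tables gave -3.23 for cytokines minus negative regulators (adjusted p = 0.0369, range 0.0369 to 0.202), against -1.62 with protein-coding transcripts, -1.67 with means and -1.95 with the filter. Chemokines minus interferon-stimulated genes became -2.35 with CPM and -2.27 with means, but -1.06 in the read-based tables and -0.70 with protein-coding transcripts (adjusted p range 0.00273 to 0.264). Macrophage identity minus neutrophil and dendritic cell markers was 8.15 and 7.97 with a pseudocount of 0.1, and ribosomal proteins minus noncoding RNAs was -3.95 with CPM and -3.53 with means, all past the threshold as before. Antimicrobial effectors minus alternative activation markers passed at 7.29 (pseudocount 0.1), 5.53 (read-based), 6.14 (CPM), 4.02 (means) and 5.14 (protein-coding transcripts), and ran from 4.86 to 5.31 with a library left out (adjusted p range 0.00273 to 0.555, the highest at 1.88 with the filter). Glycolysis minus oxidative phosphorylation turned positive at 0.16 (posterior mean TPM), 0.59 (CPM), 0.27 (means) and 0.031 (protein-coding transcripts), with no adjusted p below 0.360. Cholesterol efflux minus synthesis passed at 2.68 (read-based), 2.41 (means) and 2.36 (protein-coding transcripts). The retained-intron share was 49.7% when pooled over genes. Genes that differ between quantifications numbered 11109 with a pseudocount of 0.1 and 3146 at 4-fold. The filter left no neutrophil or dendritic cell markers to compare, and protein-coding transcripts no noncoding list. Lists were compared within each library, and no libraries of different groups could be paired, because the design has 1 group.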

Other observations

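The test of retained-intron shares in this part was chosen after the result was seen. Inducible genes, the eligible members of the immediate-early, cytokine, chemokine and interferon-stimulated lists, had a median retained-intron share of 55.3% (27 genes), and macrophage identity genes 34.4% (10 genes). The 27 held 16 interferon-stimulated, 6 chemokine, 4 immediate-early and 1 cytokine gene. A hypothesis is that recently transcribed genes may carry more retained-intron signal. The difference was 20.9 percentage points with a two-sided permutation p of 0.0531 over genes, so the test did not pass and the hypothesis stays open. Ribosomal protein genes, which are not in the inducible lists, had a higher median share, 73.1% (16 genes). Negative regulators of Toll-like receptor and NF-kB signalling, also outside those lists, had a median of 35.6% (13 genes), near that of the identity genes. The difference therefore holds only for the lists called inducible here, and a set that includes the negative regulators was not tested.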
